A study of Mus musculus with 16 samples.

How the data were processed

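Total RNA of whole colon from male C57Bl/6J mice was hybridised to Illumina 1-colour bead arrays after amplification and biotin labelling of the RNA, per the labels' protocols. The 16 samples were grouped by the treatment in their titles: 4 untreated controls, 6 given DSS and 6 given DSS with MTA. Their replicate numbers come from the titles.

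The deposited values used are the authors' probe intensities for 25697 probes, on a linear scale. The software, background treatment and normalization behind them are not given in the sources used here. The array medians were 112.012 to 112.22 and the sorted values of the arrays nearly coincided in the middle of their range, so the authors had normalized between arrays. No value was below 42.017, so any background left in the deposited intensities makes the fold changes of dim probes smaller than they were. Log2 of the deposited intensities was taken here without further normalization. The un-normalized signals and detection p-values were not used here: the 32 columns of that table are named by array position only and were given to no sample. The original plan was to correct background and normalize those signals with detection p-values, with the authors' values as an alternative and, without detection p-values, normexp correction and quantile normalization as the fallback. The first could not be done, so the authors' intensities became the source of all results, and array slides could not be tested as a batch. Because those intensities were already normalized, the fallback's normexp and quantile steps were not applied to them, a choice made after the data were seen, and each was run as an alternative.

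Gene names came from the platform annotation: 23978 probes had 1 gene symbol, 0 had several and 1719 were unnamed. The names were checked through gene identifiers against the RefSeq table of mouse assembly GRCm38.p6, which held 23962 of the named probes' identifiers and changed 0 symbols. No genome coordinates were used. As the detection filter could not be run, the fallback of the plan was used: the 50% of probes with the highest mean were kept (12848, with a mean log2 intensity from 6.82), and for each gene the probe with the highest mean was taken, leaving 9770 features, 9056 of them named. For 2250 genes more than 1 probe was kept. Among the genes with the largest changes that had several kept probes, all probes had the same sign.

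Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means over all 16 arrays, no covariate), with Benjamini-Hochberg adjustment over the 9770 features and a threshold of 0.05. Standard errors are those of the fit. All limma and permutation tests were two-sided. In simulated data with 200 changed features, the same steps found 46.3% of changes of 0.5 on the log2 scale and 82.1% of changes of 1 for DSS against control, 56.7% and 80.6% for DSS with MTA against DSS, and 35.8% and 80.6% for DSS with MTA against control, and 11 of 161, 7 of 164 and 7 of 149 calls were false. The simulated features varied independently of each other, while those of the real arrays vary together, so these shares need not hold for the real data.

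The text names the 10 genes with the largest rise and the 10 with the largest fall past the threshold (5 each for DSS with MTA against control, and all that passed where fewer did), and in each gene list up to 4 members with the smallest p in that comparison (up to 8 and Mtap for the list on MTA). This rule and 34 gene lists with 707 different genes were fixed before the data were examined, and 462 of these genes were measured. Of the lists, 32 had at least 3 measured members and were tested. The mast cell and eosinophil list and the red blood cell list (1 gene, which passed over all genes in no comparison) were not. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 32 lists per comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run beside it. By fry 17, 5 and 11 lists passed for DSS against control, DSS with MTA against DSS and DSS with MTA against control. Of 19 lists past the preset test for DSS against control, 3 held with an estimated correlation, of 13 for DSS with MTA against DSS, 0 did, and of 17 for DSS with MTA against control, 3 did. Counts "adjusted over the list alone" use only the list's members. Some lists share genes, such as Mmp10 in the matrix and injury lists and Lcn2 in the acute-phase and neutrophil lists.

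The colitis score used genes past the threshold between the mean of both treated groups and control, so the direction of the MTA difference did not enter the choice. The fit held the 3 groups apart, so genes that differ between DSS and DSS with MTA could pass more easily. The score was tested by exact permutation of the 12 treated arrays, with the genes kept as chosen. The alternatives covered scaling, filters, probes per gene, groups in the fit, array weights, the variance model, a replicate block and each array left out, and others were added after the data were seen. Figures were drawn with matplotlib 3.10.9.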

Results

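The colons of male C57Bl/6J mice were profiled on Illumina bead arrays, which read each gene through 1 or more probes, with 1 array per colon sample. Dextran sulfate sodium (DSS) is a sulfated polysaccharide that injures the colon lining of mice and is used to bring on colitis. Methylthioadenosine (MTA) is a sulfur-containing nucleoside made in the polyamine pathway. The 16 arrays covered 4 untreated controls, 6 samples of mice given DSS and 6 of mice given DSS and MTA, so the number of arrays limited the precision. The highest array median was 112.2 intensity units and the lowest 112.012, and single values ran from 42.017 to 41634. Correlations between arrays of the same group were 0.910 to 0.991 over all kept features, and no arrays were identical. The labels do not say that each sample came from a separate animal, so the p-values below measure the spread between these samples.

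The comparison of DSS with control asked what the colitis treatment did to the colon. Among genes past the threshold, the largest estimated rises were in Reg3g, an antibacterial lectin of the gut lining, with a log2 fold change of 5.91 ± 1.20 (SE, limma adjusted p = 0.00483), and in the matrix-degrading enzymes Mmp3 (5.77 ± 0.33, adjusted p = 8.88e-08), Mmp10 (5.53 ± 0.43) and Mmp13 (4.76 ± 0.49). Rises were also estimated for Wfdc12 (4.27 ± 0.58), the neutrophil-attracting chemokine Cxcl1 (4.26 ± 0.38) and the goblet cell product Retnlb (4.15 ± 0.61). The calprotectin subunit S100a8 (3.93 ± 0.47), Ly6m (3.92 ± 0.51) and the cytokine Il11 (3.90 ± 0.42) rose as well. In controls, the means of Mmp3, Mmp10, Wfdc12, Cxcl1, S100a8, Il11 and the genes Tnf, Ccl7, Lcn2, S100a9, Clec4d, Chil3, Clec7a and Hdc named further on lay at log2 intensities of 5.95 to 6.72, below the array medians of 6.81, as did Nox1 (6.59) and Lgr5 (6.35) with DSS and Lgr5 (6.72) with DSS and MTA. Their fold changes against control therefore depend on the background left in the intensities, and the order of the rises is not resolved. Mmp3 stood at a log2 intensity of 6.36 ± 0.25 (SD, n = 4) in controls and 12.12 ± 0.61 (SD, n = 6) with DSS. Among genes past the threshold, the largest falls were in Cyp4b1, a cytochrome P450 (-2.52 ± 0.56), Naaladl1 (-2.28 ± 0.51), Odf3b (-2.13 ± 0.26), and Cdo1, which oxidises cysteine (-1.99 ± 0.30). The sulfotransferase Sult1a1 (-1.92 ± 0.41), the phosphate transporter Slc34a2 (-1.91 ± 0.36), the glutathione transferase Gsta3 (-1.85 ± 0.27), Nxpe2 (-1.81 ± 0.55), the oxidase Nox1 (-1.60 ± 0.50) and the carboxylesterase Ces1e (-1.57 ± 0.40) fell as well. All 10 rises and 8 of the 10 falls separated every DSS array from every control array, and Nxpe2 and Nox1 did so in 3 and 5 of 6 DSS arrays. In all, 1423 of 9770 features changed, 848 higher and 575 lower, and 297 rose and 49 fell by over 2-fold. The count was 797 without control replicate 3 and 888 without control replicate 4. It was 2577 with array weights (1280 higher and 1297 lower), 844 with the upper 25% of probes and 780 with smooth muscle markers as a covariate. The call of Ces1e was lost without control replicate 1, and those of Nxpe2 and Nox1 were each lost in 7 of the 16 fits that left out an array.

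The 7 lists of inflammation and innate immunity passed camera upward, and 3 of them did so with an estimated correlation as well. Of 19 measured inflammatory cytokines and chemokines, 17 rose over all genes and 17 adjusted over the list alone, with a median log2 fold change of 2.20 (camera adjusted p = 4.51e-19, and adjusted p = 0.00798 with an estimated correlation). Tnf rose by 1.69 ± 0.14, Il1b by 3.32 ± 0.32 and the monocyte chemokine Ccl7 by 3.11 ± 0.30. Of 16 acute-phase and antimicrobial genes, 10 rose (12 adjusted over the list alone), among them the siderophore-binding Lcn2 (3.64 ± 0.53) and S100a9 (3.44 ± 0.54), with an adjusted p of 0.00245 with an estimated correlation. Neutrophil markers rose in 8 of 10 cases (8 adjusted over the list alone; adjusted p = 0.0442 with an estimated correlation), including the lectin receptor Clec4d (1.79 ± 0.22) and the gelatinase Mmp9 (1.53 ± 0.22). Among 18 interferon-response genes 15 rose (17 adjusted over the list alone) with a median of 1.24, such as Gbp2 (1.96 ± 0.30), Igtp (1.78 ± 0.28) and Ifit2 (2.43 ± 0.42). That list's camera call (adjusted p = 3.09e-12) was lost at an adjusted p = 0.0788 with an estimated correlation. Macrophage and monocyte markers rose in 6 of 16 cases (11 adjusted over the list alone), with Chil3 at 1.84 ± 0.31 and the fungal receptor Clec7a at 1.71 ± 0.30. The list gave adjusted p = 8.20e-07 by camera and adjusted p = 0.216 with an estimated correlation. NF-kappaB target genes rose in 11 of 16 cases (11 adjusted over the list alone), among them Tnfaip2 (2.33 ± 0.28) and the adhesion molecule Icam1 (1.23 ± 0.19). Complement and coagulation genes rose in 6 of 12 (8 adjusted over the list alone), among them C4b (2.04 ± 0.33) and the urokinase receptor Plaur (1.37 ± 0.12). Both lists passed camera (adjusted p = 2.00e-07 and 7.06e-07) and missed the threshold with an estimated correlation (adjusted p = 0.0905 and adjusted p = 0.134). No member of the T and NK cell list (8 measured), the B and plasma cell list (10 measured) or the class II antigen presentation list (11 measured) changed, and these lists did not pass camera (adjusted p = 0.927, 0.927 and 0.287). Of the 2 measured mast cell and eosinophil markers, Hdc, which makes histamine, rose by 2.40 ± 0.31, and the list was too short to test.

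Lists of matrix and vessel genes passed camera upward with DSS. Extracellular matrix and remodelling genes rose in 19 of 25 cases, and in 25 adjusted over the list alone, with a median of 1.34 (camera adjusted p = 1.68e-19, adjusted p = 0.0788 with an estimated correlation). Beside the metalloproteinases, their inhibitor Timp1 rose by 3.75 ± 0.38. Endothelial markers rose in 11 of 17 cases (15 adjusted over the list alone; median 0.70), for example Eng (1.02 ± 0.16) and Plvap (1.16 ± 0.24), with camera adjusted p = 1.16e-09 and adjusted p = 0.191 with an estimated correlation. Enteric neuron and glia markers rose in 2 of 12 cases, the receptor Ret (1.01 ± 0.20) and the tachykinin precursor Tac1 (1.55 ± 0.35), and smooth muscle markers in 2 of 16, Hspb6 (0.89 ± 0.19) and Acta2 (0.26 ± 0.08). Adjusted over the list alone, 4 and 2 members rose. Both lists passed camera (adjusted p = 2.15e-04 and 0.00299) and not with an estimated correlation (adjusted p = 0.338 and adjusted p = 0.507), and smooth muscle markers were above the control mean in 5 of 6 DSS arrays. The call of Acta2 was lost in 6 of the 16 fits that left out an array.

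The RNA was of whole colon, so no change is assigned to a cell type. Of the epithelial lists, injury-associated epithelial genes rose in 6 of 16 cases (6 rose and 1 fell adjusted over the list alone), including the alarmin Il33 (2.20 ± 0.31) and Cldn4 (1.23 ± 0.32), with camera adjusted p = 1.08e-04 and adjusted p = 0.0788 with an estimated correlation. The Wnt-responsive crypt base genes Lgr5 (-1.44 ± 0.26) and Axin2 (-1.26 ± 0.31) fell, 2 of 8 measured stem and crypt base markers over all genes and over the list alone, without a list call (adjusted p = 0.0620). Among lists of metabolism and proliferation, xenobiotic and steroid metabolism genes fell in 11 of 28 cases (16 adjusted over the list alone; median -0.80), for example Gstm1 (-1.04 ± 0.17) and Cyp2s1 (-1.05 ± 0.18). Oxidative phosphorylation genes fell in 10 of 22 (11 adjusted over the list alone; median -0.47), for example Ndufb5 (-0.92 ± 0.22) and Uqcrc1 (-0.53 ± 0.13). Cell cycle genes fell in 4 of 20 (7 adjusted over the list alone; median -0.55), for example Pcna (-0.64 ± 0.17) and Mcm5 (-1.29 ± 0.41). In fatty acid oxidation and ketogenesis 4 of 19 genes fell, such as Bdh1 (-0.62 ± 0.14), and 1 rose, the same numbers adjusted over the list alone. These 4 lists passed camera (adjusted p = 4.29e-07, 1.09e-06, 0.00198 and 0.0356) and lost the call with an estimated correlation (adjusted p = 0.134, 0.284, 0.591 and 0.591). Absorptive colonocyte markers went both ways, 3 lower and 1 higher of 23 over all genes and over the list alone, with Car2 at -1.23 ± 0.34 and Aqp4 at 1.61 ± 0.51. Aqp4 and Mcm5 each lost their call in 12 of the 16 fits that left out an array, Car2, Cldn4 and Pcna each without control replicate 3 or 4, and Ndufb5 without control replicate 4. The fatty acid oxidation list lost its camera call without control replicate 1 or DSS replicate 3. In the unfolded protein response list 2 of 15 genes rose (4 adjusted over the list alone), with Chac1, which breaks down glutathione, at 1.60 ± 0.23. In hypoxia and glycolysis 3 of 16 rose (3 adjusted over the list alone), with hexokinase Hk2 at 1.38 ± 0.19, and among immediate early genes 6 of 13 (7 adjusted over the list alone), with Junb at 1.45 ± 0.17 and Ier3 at 1.79 ± 0.20. These 3 lists passed camera upward (adjusted p = 0.00305, 0.00911 and 3.40e-06) and missed with an estimated correlation (adjusted p = 0.284, 0.301 and 0.129). The remaining lists did not pass camera. Goblet cell genes had 2 higher and 1 lower of 15 (adjusted p = 0.0736), and tight junction genes 1 higher and 2 lower of 14 (adjusted p = 0.927), the same numbers adjusted over the list alone. No member changed among adipocyte markers (11 measured, adjusted p = 0.0736), enteroendocrine markers (12 measured, adjusted p = 0.927) or skeletal muscle markers (4 measured, adjusted p = 0.927).

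Genes that handle MTA were looked at in all comparisons. Mtap, the phosphorylase that splits MTA, differed from control by 0.18 ± 0.13 with DSS (adjusted p = 0.377) and from DSS by -0.11 ± 0.12 with DSS and MTA (adjusted p = 0.677), and neither passed the test. Of 19 measured genes of methionine salvage, the methionine cycle and polyamines, 2 rose and 3 fell with DSS (2 and 4 adjusted over the list alone). Smox, which oxidises spermine, rose by 1.24 ± 0.13 and Sat1, which acetylates polyamines, by 0.45 ± 0.09, while the salvage enzymes Adi1 (-0.63 ± 0.15) and Enoph1 (-0.49 ± 0.14) and the hydrolase Ahcy (-0.77 ± 0.24) fell. The call of Ahcy was lost in 8 of the 16 fits that left out an array, and that of Enoph1 in 3. No member differed between DSS with MTA and DSS alone over all genes or over the list alone, with Smox at -0.28 ± 0.12, Mat2b at -0.22 ± 0.09 and Ahcy at 0.38 ± 0.21. Among 9 arginine methyltransferase genes, whose enzymes MTA inhibits, none changed in any comparison, and among 9 adenosine genes 1 fell with DSS, the nucleotidase Entpd5 (-0.76 ± 0.19, lost without control replicate 1). The 3 lists passed camera in no comparison (adjusted p from 0.4004 to 0.935). By fry, only the adenosine list for DSS against control passed (fry adjusted p = 0.0449).

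**Figure D1:**
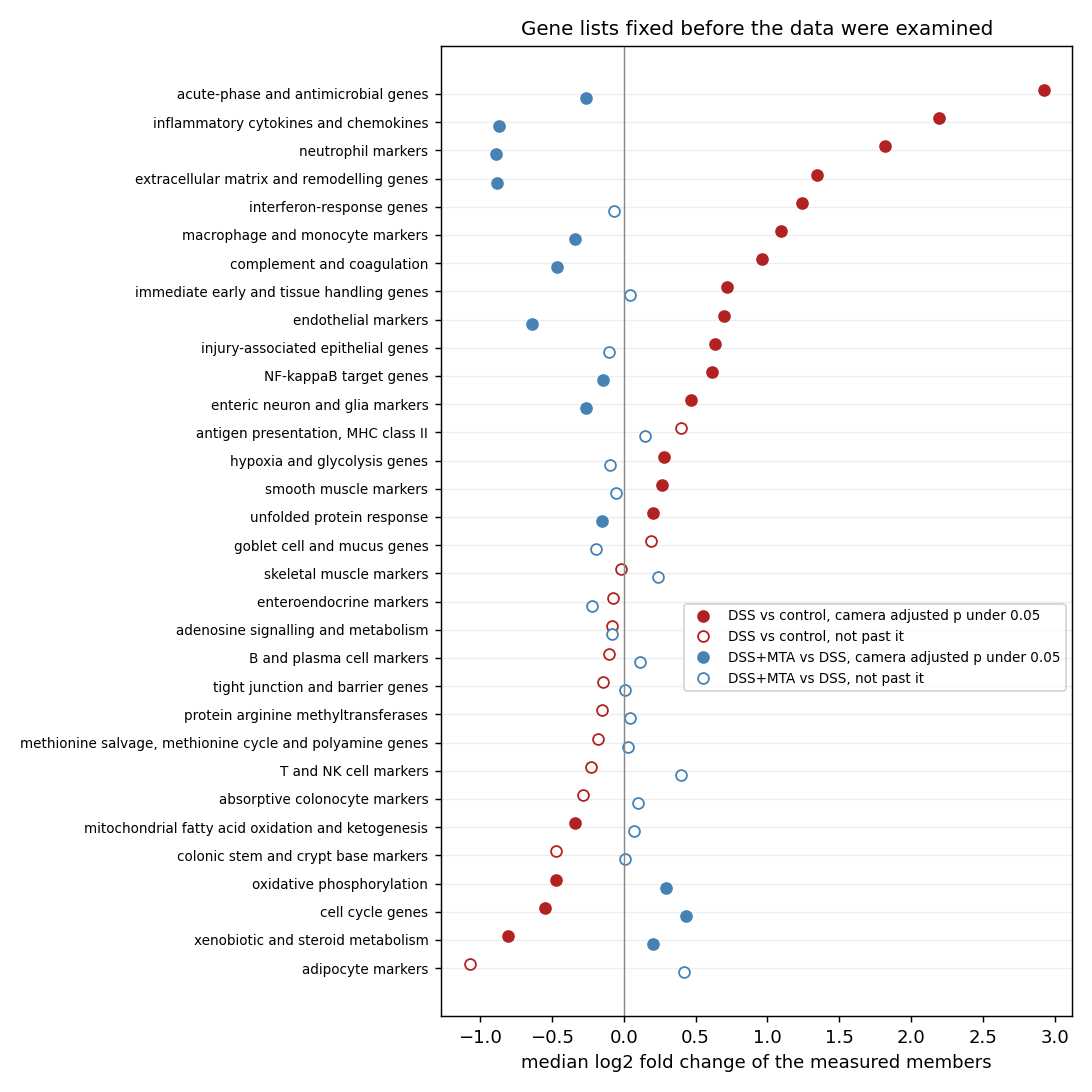
Median log2 fold change (horizontal axis) of the measured members of 32 gene lists, for DSS against control (red) and DSS with MTA against DSS (blue). Filled points passed camera with a preset correlation. The matrix list lay at 1.34 and -0.88, and the interferon list at 1.24 and -0.06.

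The comparison of DSS with MTA against DSS asked what MTA changed in the colons of DSS-treated mice. Among genes past the threshold, the estimated falls were largest in the matrix enzymes Mmp10 (-2.18 ± 0.38, limma adjusted p = 0.0309) and Mmp3 (-1.86 ± 0.29, adjusted p = 0.0171) and the protease inhibitor Serpina3n (-1.78 ± 0.37, adjusted p = 0.04997). The eosinophil chemokine Ccl11 (-1.53 ± 0.30), the macrophage product Chil3 (-1.52 ± 0.27), the matrix enzyme Adamts4 (-1.49 ± 0.21, adjusted p = 0.0118) and the endothelial adhesion molecule Selp (-1.47 ± 0.22, adjusted p = 0.0118) followed. Chil3 with MTA had a mean of 6.55, below the array medians, so the size of its fall depends on background. The monocyte chemokines Ccl2 (-1.39 ± 0.28) and Ccl7 (-1.29 ± 0.27, adjusted p = 0.04997) and the collagen Col18a1 (-1.37 ± 0.26) fell as well. Gsta3 rose by 1.37 ± 0.24 (adjusted p = 0.0309), the carbonyl reductase Dcxr by 0.71 ± 0.13, Bspry by 0.43 ± 0.08, the tight junction gene Cldn7 by 0.42 ± 0.08 and the small GTPase Arf6 by 0.36 ± 0.07. Each of these 10 falls and 5 rises lay beyond the DSS mean in 6 of 6 arrays. Mmp3 stood at a log2 intensity of 10.26 ± 0.62 (SD, n = 6) with MTA, between the control and DSS levels. In all, 37 of 9770 features differed, 31 lower and 6 higher, and 1461 had an unadjusted p under 0.05. All 31 that were lower had risen with DSS, and 2 of the 6 that were higher had fallen with it. Because the DSS arrays enter both comparisons, opposite signs are favoured without any effect. They were found in 100% of the 37, against 90.8% on average in 100 simulations with no effect. In 20 splits, different DSS arrays served each comparison, so no shared array favoured opposite signs. Of the 37 features with the smallest p in each split, a median of 91.9% then had opposite signs (75.7% to 100%). Genes that rose in one part of the DSS arrays were lower with MTA than in the other part. The median log2 difference of these genes was -0.375 (-0.591 to -0.206 over the splits).

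These calls were few, and their number changed with the model. With only the 2 groups compared in the fit, limma called 0 features (1236 had an unadjusted p under 0.05). The upper 25% of probes gave 5 features and the accession-order block 21. Array weights gave 224, the replicate block 253, smooth muscle markers as a covariate 270 and Hox genes as a covariate 99. The count was 24, 17, 11 and 23 without control replicates 1 to 4, 20, 8, 12, 18, 8 and 105 without DSS replicates 1 to 6, and 12, 208, 8, 19 and 5 without DSS with MTA replicates 1, 2, 3, 4 and 6. Of the genes named here as changed, Adamts4 and Selp kept their call whichever array was left out, Mmp3 lost it without DSS with MTA replicate 6, and each of the other 14 lost it in 5 to 14 of the 16 fits.

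Of the 32 lists, 13 passed camera, 10 downward and 3 upward, and 0 passed with an estimated correlation. Extracellular matrix genes had a median of -0.88, with 3 of 25 lower over all genes (Mmp10, Mmp3 and Col18a1) and 20 adjusted over the list alone. All 25 were below 0, with the crosslinking enzyme Lox at -1.63 ± 0.37. The mean of the list was 1.89 ± 0.40 (SD, n = 6) above control with DSS and 0.892 ± 0.454 (SD, n = 6) with MTA added, and all 6 arrays with MTA lay below all DSS arrays. Endothelial markers had a median of -0.64, with 1 of 17 lower over all genes (Emcn, -0.62 ± 0.13) and 17 adjusted over the list alone. Plvap was at -0.96 ± 0.21 and Pecam1 at -0.75 ± 0.19. Cytokines and chemokines had a median of -0.87, with 3 of 19 lower (Ccl11, Ccl2 and Ccl7) and 11 adjusted over the list alone, and Il1b at -1.31 ± 0.29 (adjusted p = 0.0587). Neutrophil markers had a median of -0.89, with 1 of 10 lower (Clec4d, -0.97 ± 0.19) and 7 adjusted over the list alone, Lcn2 at -2.14 ± 0.47 and Fpr2 at -1.06 ± 0.26. These 4 lists passed camera (adjusted p = 5.58e-19, 7.00e-16, 2.34e-10 and 1.58e-06), and none did with an estimated correlation (adjusted p = 0.111, 0.132, 0.111 and 0.111). Acute-phase genes (median -0.26, mean -0.70), complement and coagulation (median -0.46), macrophage markers (-0.34), NF-kappaB targets (-0.15), enteric neuron and glia markers (-0.26) and the unfolded protein response (-0.15) also passed camera downward (adjusted p from 8.93e-05 to 0.0255) and missed with an estimated correlation (adjusted p from 0.111 to 0.711). Left out singly, some arrays ended the call of the macrophage list (2 of 16 fits: DSS replicate 5 and DSS with MTA replicate 6), the NF-kappaB list (3 fits: DSS replicate 6 and DSS with MTA replicates 1 and 6), the enteric neuron and glia list (4 fits: DSS replicates 3 and 6 and DSS with MTA replicates 1 and 4) and the unfolded protein response list (3 fits: DSS replicate 1 and DSS with MTA replicates 1 and 3). The highest adjusted p in these fits were 0.130, 0.190, 0.209 and 0.169. Among their members Chil3 fell, and 4, 5, 1, 0, 0 and 0 members were lower adjusted over the list alone.

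Upward, oxidative phosphorylation genes had a median of 0.29, with 20 of 22 above 0 and Atp5o, a subunit of ATP synthase, at 0.47 ± 0.18. Cell cycle genes had a median of 0.43, with 20 of 20 above 0 and Mcm7 at 0.61 ± 0.27. No member of either list passed over all genes or over the list alone. Xenobiotic metabolism had a median of 0.20, with Gsta3 higher and 3 of 28 higher adjusted over the list alone. These 3 lists passed camera (adjusted p = 4.76e-05, 0.00120 and 0.00740) and lost the call with an estimated correlation (adjusted p = 0.634, 0.723 and 0.634). The xenobiotic list also lost it without DSS replicate 3 or DSS with MTA replicate 3 (highest adjusted p = 0.0704). Interferon-response genes did not move together: 8 of 18 lay above 0 and 10 below, the median was -0.06, and camera gave an adjusted p = 0.875. Members stood both ways, with Psmb9 at 0.47 ± 0.17, Irf7 at 0.37 ± 0.18 and Cxcl10 at -0.84 ± 0.50. The smooth muscle list, a measure of how much muscle wall a sample held, had a median of -0.05 (adjusted p = 0.548), and its mean varied from sample to sample within the treated groups (SD 0.302 with DSS and 0.364 with MTA). No list of immune lymphocytes or of colon epithelial cell types passed camera (adjusted p from 0.0551 to 0.875), with Cd3d at 0.75 ± 0.38, Car2 at 0.60 ± 0.30 and Lgr5 at 0.37 ± 0.24. The same held for class II antigen presentation, injury-associated, tight junction, fatty acid oxidation, adipocyte, skeletal muscle, hypoxia and immediate early genes (adjusted p from 0.204 to 0.875). Adjusted over the list alone, 3 injury-associated genes, 2 immediate early genes and 1 stem and crypt base marker were lower, and 2 tight junction genes and 1 fatty acid oxidation gene were higher.

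A colitis score was set for each array from 723 genes that were higher and 531 that were lower when the mean of both treated groups was compared with control. The direction of the MTA difference did not enter this choice. Its size could, since the fit took the spread within each group. The permutation p of the score below does not allow for this, as the genes were not chosen anew. The score is the mean log2 value of the former minus that of the latter, relative to the control mean. It was 1.60 ± 0.18 (SD, n = 6) with DSS and 1.22 ± 0.35 (SD, n = 6) with DSS and MTA, or 76.2% of the DSS level. The difference of -0.38 had an exact two-sided permutation p = 0.0411 over 924 splits, with 0.00216 the smallest p they allow, and 5 of 6 arrays with MTA lay below the DSS mean. The risen genes alone differed by -0.30 (exact permutation p = 0.0130) and the fallen genes alone by 0.08 (exact permutation p = 0.262), and the mean of the cytokine list by -0.83 (exact permutation p = 0.00649). The call was lost, at exact permutation p from 0.0649 to 0.121, when DSS replicate 2, 3, 4 or 5 or DSS with MTA replicate 1, 3, 4 or 6 was left out, with differences from -0.388 to -0.246.

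**Figure D2:**
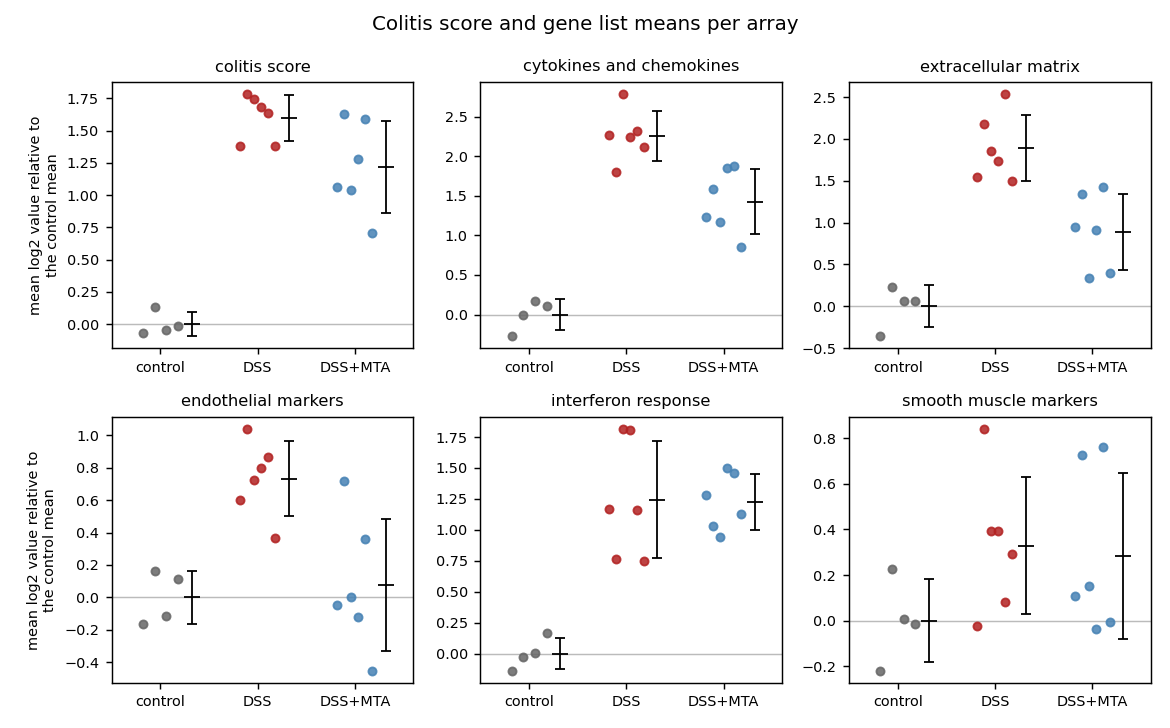
Each point is an array, and the bar beside each group is the mean ± SD (control n = 4, DSS n = 6, DSS with MTA n = 6). The vertical axes give the colitis score or the mean log2 value of a gene list relative to the control mean. The matrix list averaged 1.89 with DSS and 0.892 with MTA added, while the interferon list averaged 1.24 and 1.22.

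**Figure D3:**
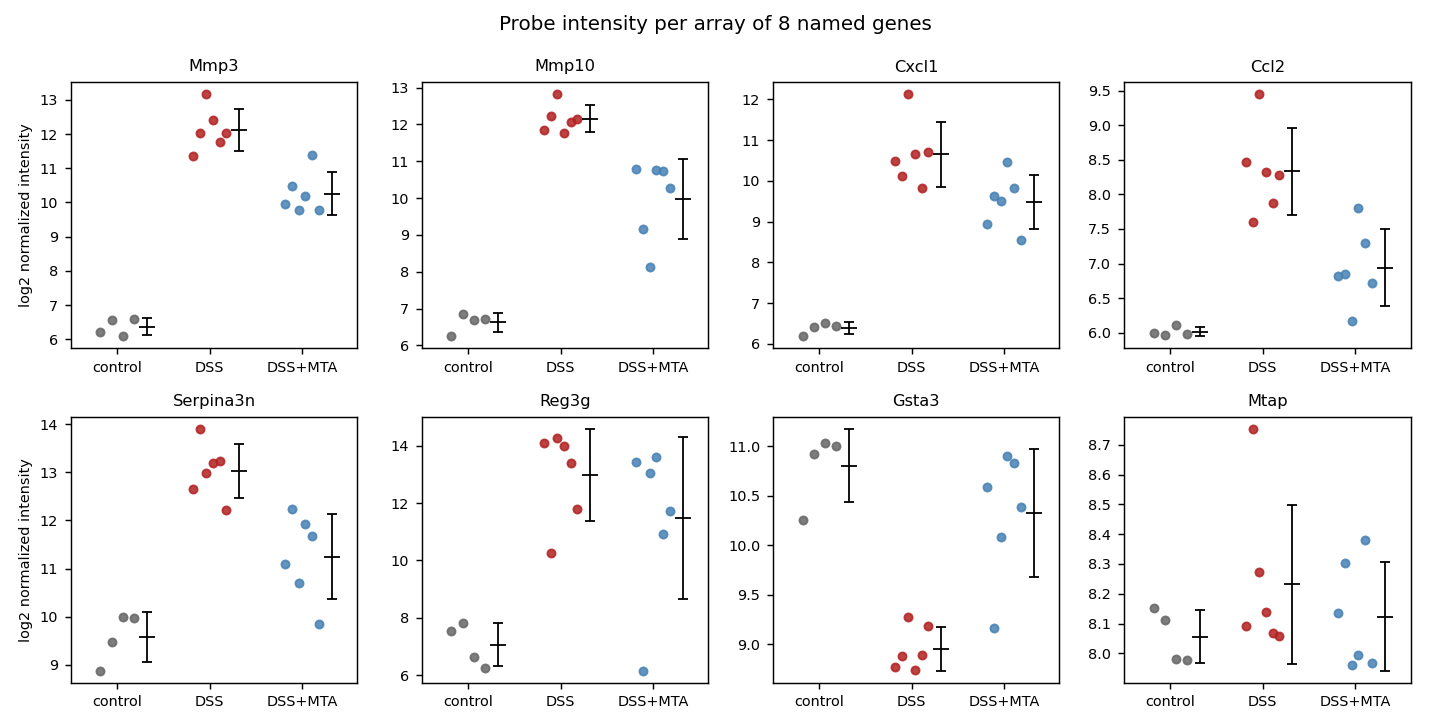
Log2 normalized intensity (vertical axes) of the probe used for 8 genes, with each array as a point and the mean ± SD beside each group. Mmp3 and Mmp10 were lower with MTA than with DSS alone, Gsta3 was higher, and Mtap did not pass the test in either comparison.

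The comparison of DSS with MTA against control asked what still differed from the untreated colon. Reg3g (4.42 ± 1.20, adjusted p = 0.0461), Mmp3 (3.90 ± 0.33, adjusted p = 1.39e-05), Retnlb (3.76 ± 0.61), Ly6m (3.68 ± 0.51) and Mmp10 (3.35 ± 0.43) had the largest estimated rises among genes past the threshold. Their order was not resolved because Mmp3 and Mmp10 were below the array medians in controls. Nxpe2 (-2.39 ± 0.55), Cyp4b1 (-2.24 ± 0.56), Sult1a1 (-1.61 ± 0.41), Odf3b (-1.51 ± 0.26) and the sulfotransferase Sult1c2 (-1.51 ± 0.39) had the largest falls among genes past the threshold. Interferon-response genes rose in 12 of 18 cases (18 adjusted over the list alone; median 1.14), for example Igtp (1.92 ± 0.28) and Tap1 (1.14 ± 0.17). Cytokines and chemokines rose in 10 of 19 (15 adjusted over the list alone; median 1.19), for example Tnf (1.47 ± 0.14) and Cxcl1 (3.09 ± 0.38), and acute-phase genes in 5 of 16 (10 adjusted over the list alone), for example S100a8 (2.58 ± 0.47). These 3 lists passed camera with the preset (adjusted p = 1.48e-17, 9.74e-15 and 4.85e-08) and with an estimated correlation (adjusted p = 0.0473, 0.0229 and 0.00352). Matrix genes rose in 5 of 25 cases (6 adjusted over the list alone), among them Timp1 (2.29 ± 0.38) and Mmp13 (2.88 ± 0.49), and passed camera (adjusted p = 1.79e-08; adjusted p = 0.282 with an estimated correlation). None of the 17 endothelial markers changed over all genes or over the list alone, with Eng at 0.48 ± 0.16 and a list adjusted p = 0.2497. The stem cell receptor gene Lgr5 (-1.07 ± 0.26) and the salvage enzyme Adi1 (-0.79 ± 0.15) fell, Lgr5 to a mean below the array medians, while Smox rose by 0.95 ± 0.13. Of the other lists, NF-kappaB targets, complement and coagulation, neutrophil, macrophage, injury-associated, smooth muscle, enteric neuron and glia, hypoxia and immediate early genes passed camera upward (adjusted p from 6.55e-07 to 0.0129), and xenobiotic metabolism, oxidative phosphorylation, fatty acid oxidation and stem and crypt base markers passed downward (adjusted p from 3.40e-05 to 0.0309). With an estimated correlation these 13 lists missed the threshold (adjusted p from 0.0707 to 0.571). The camera call was also lost for stem and crypt base markers without control replicate 2, for enteric neuron and glia markers without DSS with MTA replicate 2 or 5, and for fatty acid oxidation without control replicate 1 or DSS with MTA replicate 2 or 5 (highest adjusted p = 0.0870, 0.0693 and 0.457).

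In all, 448 features differed from control with DSS and MTA, 283 higher and 165 lower, and 17 of 32 lists passed camera, 13 upward and 4 downward. The count was 249, 158 and 205 without control replicates 2, 3 and 4, 243 without DSS with MTA replicate 5 and 721 without replicate 6. It was 1088 with array weights, 831 with Hox genes as a covariate and 289 with the upper 25% of probes. Reg3g lost its call in 14 of the 16 fits that left out an array, Sult1c2 in 8, Sult1a1 in 7, Cyp4b1 in 6, and Nxpe2 in 3, and Lgr5, kept by the filter in 11 of these fits, lost it without DSS with MTA replicate 2 or 5. Of the 448, 349 had also changed in the same direction with DSS alone. The same controls enter both comparisons: simulations with no effect gave 234.3 shared features among lists as long, and independent lists would share 34.3. The simulated lists held the top-ranked features whether or not they passed the threshold. They show that shared controls favour overlap, and do not give the part of the 349 that comes from sharing. With different controls in each comparison, 12 to 69 features passed for DSS with MTA, of which 8 to 26 also passed with DSS alone in the same direction. Each of these fits held 2 controls and only the groups compared, so its counts cannot be set against 448 or 349.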

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

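All values in this part were found by a search for arrays that lay far from the others of their group, by Dixon's criterion, and the tests on the spread between arrays and on other groupings of the samples were all chosen after the results were seen. The search covered 99 values of the score and the lists, of which 2 stood apart, and 303 values of 101 genes, of which 10 did; chance alone gives about 5%. These values are thus no more frequent than chance gives, and no cause was tested for them.

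Among controls, Gsta3 had a log2 intensity of 10.25 in replicate 1 against 10.92 to 11.04 in the others, and Il11 had 6.49 in the same array against 6.67 to 6.70. Cldn7 was at 10.48 in control replicate 2 against 10.29 to 10.32, Ccl2 at 6.11 in control replicate 3 against 5.97 to 5.99, and Odf3b at 8.88 in control replicate 4 against 9.28 to 9.32. The mean of the skeletal muscle list, relative to the control mean, was -0.27 in control replicate 4 against 0.08 to 0.11. Among DSS arrays, Mtap was at 8.75 in replicate 2 against 8.06 to 8.27, and Entpd5 at 11.23 in replicate 6 against 10.69 to 10.89. Among arrays of DSS with MTA, Acta2 was at 14.91 in replicate 3 against 15.03 to 15.10, Atp5o at 10.48 in replicate 4 against 9.72 to 9.96, and the tight junction list at -0.47 in replicate 2 against -0.07 to 0.16. Reg3g was at 6.15 in replicate 2 of DSS with MTA against 10.91 to 13.62 in the other arrays of that group, below its control mean of 7.06 ± 0.75 (SD, n = 4).

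The array of DSS with MTA replicate 2 also lay at the far end of the main axis of spread within groups, which held 41.9% of that spread over all features. Position along the colon is a candidate explanation: a score of posterior minus anterior Hox genes, which pattern the gut from front to back, followed the axis over 16 arrays (Pearson r = 0.721, permutation p = 0.0016, adjusted p = 0.0032 over 4 relations; Spearman rho = 0.662, permutation p = 0.0064; r = 0.570 without the 2 farthest arrays), though 1 of 3 posterior genes (Hoxa13) and 11 of 13 anterior genes, such as Hoxb6 (r = -0.932), went the way it needs. The share of muscle wall may contribute as well, since smooth muscle markers followed the axis too (Pearson r = 0.788, permutation p = 0.00032, adjusted p = 0.00128; Spearman rho = 0.674, permutation p = 0.0054; r = 0.731 without the 2 farthest). Severity of colitis stays open: the SD of controls along the axis was 53.6% of that of treated arrays, with a 95% interval from 24.4 to 204, and the colitis score gave r = 0.549 (permutation p = 0.028, adjusted p = 0.0373) and rho = 0.409 (permutation p = 0.12). The labels name whole colon, which goes against a sampled segment, so position stays a hypothesis.

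Other groupings of the same arrays were tried in 100 splits per comparison, the real one included. There were 210 possible splits for each comparison with control and 462 for DSS with MTA against DSS, so most or many were not tried. For DSS against control 1 of 100 splits gave as many features as the real 1423, and the highest other gave 64. Chance is thus unlikely for this count, within the limit of the splits tried. For DSS with MTA against control 1 of 100 gave as many as 448, and the highest other gave 316. That split set all controls and DSS with MTA replicates 3 and 6 against the other arrays with MTA, so it kept much of the real contrast. The next highest gave 6. Chance is thus unlikely for this count too, within the same limit. For DSS with MTA against DSS 6 of 100 gave as many as 37, and the highest other gave 1005. That split set DSS replicates 1 and 6 and DSS with MTA replicates 1, 3, 4 and 6 against the other treated arrays. Their colitis scores were 0.709 to 1.38, against 1.59 to 1.78 in the others, so this split followed the colitis score across both groups. Chance was not excluded for the count of 37.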

How the results depend on the processing

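The scaling by quantiles, normexp background correction, the upper 25% of probes, the accession-order block, the omission of the least correlated arrays and both covariates were chosen after the data were seen. No named gene or score past its threshold reversed direction in any alternative run. The balance of the DSS against control count turned with array weights, from 59.6% higher to 49.7%. By camera's direction no list did either, but 4 medians of lists past the threshold changed sign where the call was lost: smooth muscle markers with their own score as a covariate (-0.02 for DSS against control and -0.005 for DSS with MTA against control), oxidative phosphorylation with the same covariate (0.04, DSS with MTA against control), and fatty acid oxidation without the least correlated arrays (0.03, DSS with MTA against control). Counts for the 3 comparisons (DSS against control, DSS with MTA against DSS, DSS with MTA against control) were within 1.5 times with median centring (1422, 37, 450), no filter (1356, 27, 401), every probe (1776, 46, 615), trended and robust variance (1425, 34, 443), quantile scaling (1416, 34, 449) and normexp (1423, 37, 449). With array weights they were 2577 (1280 higher, 1297 lower), 224 (26 and 198) and 1088 (596 and 492). With only the 2 groups compared, limma called 0 for DSS with MTA against DSS (0 higher, 0 lower; 1236 at an unadjusted p under 0.05), and 84 lower for DSS with MTA against control; fewer arrays estimated the spread. The upper 25% of probes gave 844 (493 and 351), 5 (2 and 3) and 289 (95 lower), with fewer genes tested, and a colitis score difference of -0.353 (exact permutation p = 0.0606). The accession-order block gave 21 (17 lower) for DSS with MTA against DSS and a score difference of -0.381 (exact permutation p = 0.0550). Without the least correlated array of each group (control 1, DSS 2, DSS with MTA 2) that comparison gave 2 higher and 47 lower. The smooth muscle covariate gave 780 (531 and 249) for DSS against control and 270 (45 and 225) for DSS with MTA against DSS. The Hox covariate gave 873 lower, 99 (18 and 81) and 831 (458 and 373). The score of fallen genes only, with its sign turned as in the full score, differed by -0.0836 (exact permutation p = 0.262); the genes themselves differed by 0.0836. Where no construction is named, the cause was not tested.

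With the replicate number as a block (replicate block), DSS with MTA against DSS gave 253 features (27 higher, 226 lower); same-number arrays correlated from -0.311 to 0.624, 7 of 14 pairs above 0.1, so the numbers were not taken as pairs.

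Leaving out each array gave 797 to 1716 for DSS against control (higher 535 to 983, lower 262 to 733), 5 to 208 for DSS with MTA against DSS (0 to 30, 5 to 183), 158 to 721 for DSS with MTA against control (117 to 392, 41 to 329) and score differences from -0.483 to -0.246. Of the genes chosen by the naming rule that passed, 54 of 68, 2 of 17 and 22 of 32 kept their call in every one of these fits that tested them (all 16, but 11 for Lgr5), and 52, 0 and 24 in every other alternative that tested them (among others, Naaladl1 and Uqcrc1 lost theirs without the least correlated arrays, Axin2 and Adi1 with the smooth muscle covariate, all for DSS against control). Of the lists, 18 of 19, 8 of 13 and 14 of 17 kept it in every fit that left out an array. Not run, for want of detection p-values and array positions per sample: correction of the raw signals, the stricter detection filter and the slide block. The score has no value with 2 groups, weights, trended variance or every probe. Signals near background limit fold changes: Mmp3 in controls (log2 6.36) lay below the lowest mean kept (6.82), and so did other named genes.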

Other observations

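In this part the test with Hox genes as a covariate was written before its result was seen, and the other tests were chosen after the results were seen. Outside the comparisons, DSS with MTA replicate 3 had the highest means of the T and NK cell list (1.60 on the log2 scale relative to the control mean) and of the B and plasma cell list (1.25), while the mean of the T and NK list over that group was 0.26 ± 0.72 (SD, n = 6). The adipocyte list varied from -1.88 to 1.01 between arrays. On the axis of spread within groups, the 30 genes farthest to the anterior Hox side included the bile acid transporter subunit Slc51a, the transcription factors Osr2 and Cdx2, the antibacterial lectins Reg3g and Reg3b, the disaccharidase Sis and the chloride channel Cftr. The 30 on the posterior Hox side included the proton pump Atp12a, the hormone genes Insl5, Gcg and Pyy, and the glycosyltransferase B3gnt7. These genes were chosen after their values were seen.

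Of the 15 lists raised by DSS, 5 had a lower mean per array with MTA than with DSS alone at an adjusted p under 0.05 by exact permutation: matrix genes (-0.998, p = 0.00216, the smallest these splits give, adjusted p = 0.0162; 6 of 6 arrays below every DSS array), neutrophil markers (-0.826, p = 0.00216, adjusted p = 0.0162; 6 of 6), cytokines (-0.826, p = 0.00649, adjusted p = 0.0260; 4 of 6), endothelial markers (-0.656, p = 0.00866, adjusted p = 0.0260; 5 of 6) and acute-phase genes (-0.702, p = 0.00866, adjusted p = 0.0260; 3 of 6). For the matrix, endothelial and cytokine lists, 97.2% of the mean difference of their 61 genes was left with smooth muscle markers as a covariate (exact permutation p = 0.00649). With the Hox score 96.5% was left (exact permutation p = 0.00216). Between these groups, smooth muscle markers differed by -0.0444 (exact permutation p = 0.838) and the Hox score by -0.0753 (exact permutation p = 0.823). Little could thus be removed, and the share left is no separate evidence. The close means of the muscle markers argue against a smaller share of muscle wall as the whole cause, as far as they measure it. Position along the colon was not decided, since 1 of 3 posterior genes of the Hox score followed the axis as it needs. A milder colitis was taken to lower all genes raised by DSS by the same share of their log2 rise over control. That assumption was not tested, so a departure from it would not tell milder colitis from a separate effect of MTA. No departure passed for the cytokine list, which kept 63.3% of its log2 rise with DSS, against 71.2% for the other risen genes (exact permutation adjusted p = 0.752). Neutrophil markers kept 56.4% and acute-phase genes 70.9% (exact permutation adjusted p = 0.746 and 0.991). A proportional fall stays open for matrix genes (47.2% against 71.7%, exact permutation p = 0.00433, adjusted p = 0.0649) and endothelial markers (10.5% against 71.0%, exact permutation p = 0.0152, adjusted p = 0.114). They may have fallen more than the other risen genes, but this did not pass over the 15 lists. The other risen genes were chosen with the arrays with MTA included, and the 15 lists by DSS against control alone. This favours lower shares for the lists, so part of these gaps may come from the choice.

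With MTA, interferon-response genes kept 98.4% of the log2 rise over control that they had with DSS, against 70.0% for the other risen genes. Whether they may follow the same proportional fall stays open: the departure had an exact permutation p = 0.136 and an adjusted p = 0.680.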
